A study of Homo sapiens with 12 samples.

How the data were processed

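Bulk RNA-seq libraries of HL-60 cells were compared at 4 times: before ATRA (0 h) and after 4 h, 2 d and 4 d in 1 µM ATRA, with 3 replicates per time and 12 libraries in all. The deposited values are counts, whole numbers of reads per gene and library, with 5 classes of reads that were not assigned to a gene. Per the submitters' processing notes, reads were inspected with FastQC, trimmed with Trim Galore 0.6.7, aligned to hg19 with HISAT2 2.1.0 and counted per gene with HTSeq 1.99.2. The gene annotation, the strand setting of the counting and the library kit are not given in the sources used here. Raw reads and alignments were not analysed here, and values are per gene, without isoforms.

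The files listed 26364 genes, of which 3098 had 0 reads in all 12 libraries. Reads in genes came to 7866757 in the shallowest library and 13658177 in the deepest. Reads outside any gene made up 13.97% to 28.15% of a library, ambiguous reads 2.74% to 3.9% and reads with several alignments 4.5% to 5.7%. The 20 most abundant genes held 9.4% to 13.79% of gene reads. MPO alone held 0.65% to 0.95% of them at 4 d and 2.24% to 4.35% in the other libraries. Replicates were compared by pairwise chi-square over genes with at least 20 reads, and chi-square per degree of freedom ran from 3.47 to 98.02, above the value of 1 for counting error alone. Replicates were taken as independent, which the labels neither state nor exclude.

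Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough reads by edgeR's filterByExpr were kept, 12671 genes with 99.9% of gene reads. Libraries were scaled by TMM factors, which ran from 0.864 to 1.098. A single model with 1 mean per time was fitted to all 12 libraries with a quasi-likelihood fit and 8 residual degrees of freedom. Comparisons were 4 h, 2 d and 4 d each against 0 h, 2 d against 4 h, 4 d against 2 d, and an F-test over all times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and calls of at least 2-fold are counted beside. The SE of a log2 fold change was derived from the fold change and its quasi-likelihood F statistic. Where a group had 3 reads or fewer in a gene, a fold is given as a bound, with 3 reads over the group in place of 0, or as a ratio with a 95% counting interval.

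Gene lists, 34 of them with 1032 symbols, the comparisons, the thresholds, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Lists with at least 5 tested members were used, which gave 32 lists, and adjusted p-values cover 160 tests over 5 comparisons. The list of mitochondrially encoded genes had no symbol in the files, the lymphoid list had 4 tested members, and 16 list symbols in all were absent from the files. A second camera test used the estimated correlation.

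Genes were named by a rule. For each time against 0 h, it took the 5 genes that rose most and the 5 that fell most among called genes at a mean of 10 CPM or more. These genes also needed every library of one group above every library of the other. Symbols starting with LOC, LINC, MIR, SNOR, RNU or RNA5 were left out of them. The rule added the 2 to 4 called members of each described list in order of size, or the member with the highest mean where none was called. It also added MPO, ELANE, CYBB, ITGAM, CD38, CYP26A1, CEBPE and MYC at every time. For the steps between treated times it took 3 genes in each direction, under the conditions for the largest changes. XIST and Y-linked genes were left out, several other genes that the rule names are not reported, and any gene named outside the rule is stated to be chosen after its values were seen.

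Alternatives were RLE factors, library totals alone, the 20 most abundant genes left out, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at a mean of 1 CPM, fits to 6 libraries and a fit with replicate number as a term. Further ones were an adjusted p under 0.01, a fold of at least 2, and each library left out in turn. Chosen after seeing the data were an offset for GC content and transcript length, a fit without 0 h replicate 2, 4 h replicate 1 and 4 d replicate 1, and 1 without 0 h replicate 2, 4 h replicate 3 and 4 d replicate 1. GC content and length came from GRCh38 transcripts matched by gene symbol, since no hg19 annotation was among the references used here. They were matched for 23774 genes, 90.2% of those in the files and 96.0% of the 8752 genes at a mean of 10 CPM or more. Slopes on GC content, fitted together with log2 length, used each library's log2 expression minus the mean of its group mates, with a pseudocount of 0.5 CPM.

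The tests were tried on simulated data over 12458 genes, with the depth of these libraries and 1 spread per gene for all groups. Genes were drawn independently, so shifts shared by many genes and the unequal spread of the real groups were not covered. At 4 h against 0 h, edgeR called 57 of 100 genes simulated with a log2 change of 1 and 92 of 100 with a change of 2, and 9 of 12258 unchanged genes. Camera called a simulated list of 30 shifted genes at 4 d against 0 h. Shared 0 h libraries were examined with 100 simulations of unchanged groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.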

Results

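RNA was sequenced from HL-60 cells, a human promyelocytic leukemia line that matures along the granulocyte lineage with all-trans retinoic acid (ATRA), a ligand of the retinoic acid receptors. The libraries form 4 groups of 3 replicates: cells before ATRA (0 h) and cells after 4 h, 2 d and 4 d in 1 µM ATRA. Reads assigned to genes numbered 10843263, 12077671 and 10223158 in the 0 h replicates 1, 2 and 3, and 9981906, 13533221 and 13658177 in those of 4 h. The 2 d replicates held 11562933, 13021237 and 7866757 gene reads and the 4 d replicates 10254085, 9372996 and 10965224. Every comparison between times set cells with different lengths of ATRA treatment, and of culture, against each other; no untreated library of 4 h, 2 d or 4 d was used here. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples. Levels are CPM, read counts relative to the library's gene reads after TMM scaling, as mean ± SD with n = 3 per group. Fold changes are log2 values ± SE from a fit to all 12 libraries, tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gene lists were tested with camera, and a list's count gives the called members among those measured. Members with too few reads for the filter, or absent from the files, are outside that count.

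The first principal component, with 72.5% of the variance over tested genes at 10 CPM or more, set the 2 d and 4 d libraries apart from those of 0 h and 4 h, which overlapped on it. The second component held 16.3%. It followed GC content across the 8402 of these genes with matched GC content and length (Spearman rho 0.662, genes not being independent replicates). On that axis 0 h replicate 2 lay at 56.5, 4 d replicate 1 at 34.36 and 4 h replicate 3 at 3.59, each above its group mates (-31.85 and -22.48 for the other 4 h libraries). Slopes on GC content, fitted together with length, used each library's log2 expression minus the mean of its group mates. Per 10 points they were 0.484 in 0 h replicate 2, 0.31 in 4 d replicate 1 and 0.361 in 4 h replicate 3. A library that stands apart can move the slopes of its mates the other way (-0.347 in 0 h replicate 1). In 4 h replicate 1, 22265 genes had at least 1 read, against 15198 to 15798 in the other 11 libraries. The common biological coefficient of variation within a group was 26.7% at 0 h, 20.3% at 4 h, 10.9% at 2 d and 21.9% at 4 d.

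**Figure D1:**
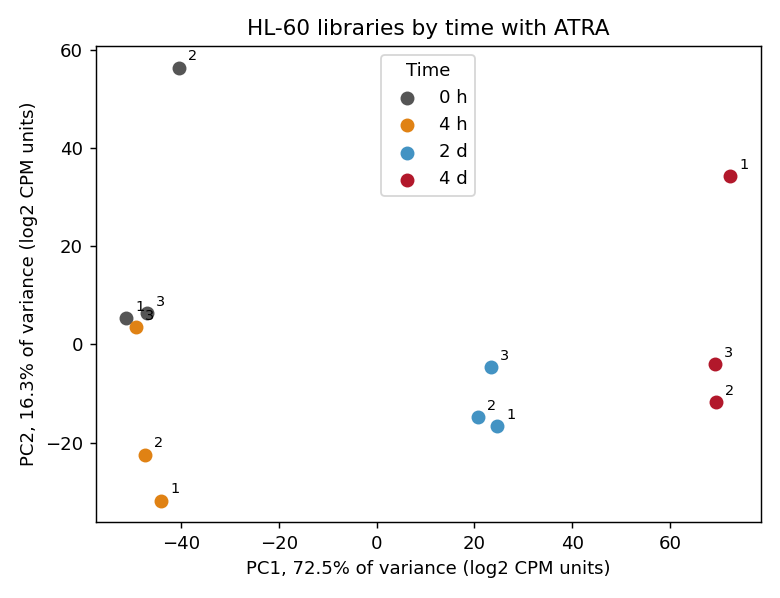
Principal components 1 and 2 of log2 CPM for the 12 libraries, 1 point per library with its replicate number, colored by time in ATRA. Component 1 (72.5% of variance) runs from 0 h and 4 h to 4 d, and 0 h replicate 2 (56.5) and 4 d replicate 1 (34.36) lie high on component 2 (16.3%).

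The first comparison, 4 h against 0 h, asked which transcripts changed within hours of ATRA. The list of the retinoic acid response shifted higher and that of Fc, complement and pattern receptors lower. CD38, an ectoenzyme that hydrolyzes NAD, rose from 1.48 ± 0.580 CPM at 0 h to 66.3 ± 15.0 at 4 h, a log2 fold change of 5.49 ± 0.34 with every 4 h library above every 0 h library. HIC1, a transcriptional repressor, rose from 1.55 ± 0.449 to 93.0 ± 26.9 CPM (5.89 ± 0.32), and TGM2, tissue transglutaminase, from 0.319 ± 0.318 to 25.4 ± 3.70 CPM (6.29 ± 0.43). CD14, the co-receptor for bacterial lipopolysaccharide, fell from 22.5 ± 2.17 to 3.12 ± 0.779 CPM (-2.84 ± 0.20). Every 4 h library lay below every 0 h library, which the rule for the largest declines required.

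Other transcripts that rose had no read at 0 h, so that only bounds can be given, with 3 reads over the group as the floor. PTGES, which makes prostaglandin E2, was at least 74.3-fold higher at 4 h, and DHRS3, which reduces retinaldehyde, at least 61.6-fold higher. BATF2, a basic leucine zipper factor, was at least 21.1-fold higher, and CYP26A1, the enzyme that clears retinoic acid, at least 6.46-fold higher. MLXIPL, a glucose-responsive transcription factor, had 1 read at 0 h and was 190-fold higher (95% counting interval 33.8 to 7550). These intervals and floors cover counting error only. In the retinoic acid response list 7 of 21 members rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.41 and camera adjusted p = 6.77e-06.

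Among myeloid transcription factors, 5 of 43 members rose and 4 fell (7 and 5 adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.708). ID1, an inhibitor of basic helix-loop-helix factors, rose by 5.39 ± 0.39, the immediate early factor EGR1 by 2.42 ± 0.25 and RUNX3 by 1.42 ± 0.24, while GATA2, a factor of early progenitors, fell (-1.19 ± 0.22). Of the cytokines and chemokines, 4 of 25 members rose and 3 fell (4 and 7 adjusted over the list alone), with camera adjusted p = 0.36. OSM, a cytokine of the interleukin-6 family, rose by 4.08 ± 0.31 and the monocyte attractant CCL2 by 2.08 ± 0.18. In the heat shock and immediate early list 2 of 25 members rose and 2 fell (4 and 6 adjusted over the list alone), with a median of 0.01, a mean of -0.08 and camera adjusted p = 0.893. FOS rose by 2.05 ± 0.18 and JUN fell (-1.67 ± 0.17). For glycolysis, 2 of 27 members rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.499). FBP1, an enzyme of gluconeogenesis, rose by 1.45 ± 0.20 and the fructose transporter SLC2A5 by 1.32 ± 0.23, while the glucose transporter SLC2A3 fell (-1.06 ± 0.20).

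Among Fc, complement and pattern receptors, 12 of 27 members fell (17 adjusted over the list alone), with a median of -0.80 and camera adjusted p = 1.72e-08. CLEC7A, a receptor for fungal glucans, fell (-2.45 ± 0.25), as did the immunoglobulin G receptor FCGR2A (-1.60 ± 0.24) and the complement receptor CR1 (-1.32 ± 0.23). In the secondary and tertiary granule list 8 of 18 members fell (9 adjusted over the list alone), with a median of -0.49 and camera adjusted p = 6.21e-05, adjusted p = 0.0757 with an estimated correlation. MMP8, neutrophil collagenase, fell (-1.62 ± 0.27). So did SLC11A1, a phagosomal metal transporter (-1.43 ± 0.28), whose call by edgeR ended without single libraries (adjusted p = 0.0607 without 4 h replicate 2, also over 0.05 without 4 h replicate 1, range over alternatives 1.01e-08 to 0.0607). Of the adhesion and chemotaxis receptors, 2 of 22 members rose and 6 fell (5 and 6 adjusted over the list alone), without a shift of the list (camera adjusted p = 0.283). The integrin ITGAX fell (-2.15 ± 0.35), as did the complement receptor C3AR1 (-1.79 ± 0.30) and the formyl peptide receptor FPR1 (-1.68 ± 0.19), while the adhesion molecule ICAM1 rose by 2.08 ± 0.22. Among monocyte and macrophage markers, 1 of 17 members rose and 5 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.000284, adjusted p = 0.109 with an estimated correlation). S100A12, a calcium-binding alarmin, fell (-2.14 ± 0.24). For eosinophil and basophil or mast markers, 1 of 9 members rose and 4 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.000751). EPX, eosinophil peroxidase, fell (-1.77 ± 0.24), as did CLC (-1.31 ± 0.17) and RNASE2 (-1.03 ± 0.16). CCR3, an eotaxin receptor, rose by 1.68 ± 0.34 by edgeR's test. Its change was 1.553 without 4 h replicate 1, where it was not called (edgeR adjusted p = 0.0563, range over alternatives 0.000205 to 0.111). The fit to the 6 libraries alone did not call it either.

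In the cholesterol synthesis and uptake list 7 of 25 members fell (11 adjusted over the list alone), with a median of -0.40 and camera adjusted p = 7.71e-07. SREBF1, a lipogenic transcription factor, fell (-2.20 ± 0.45), a change whose edgeR call ended without single libraries (adjusted p = 0.0738 without 4 h replicate 2, also over 0.05 without 4 h replicate 1, range over alternatives 1.44e-19 to 0.0738). Of the cytokine receptors, 5 of 27 members fell (5 adjusted over the list alone; camera adjusted p = 0.0441, adjusted p = 0.25 with an estimated correlation). IL2RG, the common gamma chain, fell (-1.27 ± 0.16), as did IL10RA (-1.12 ± 0.18). The call of the cytokine receptor list ended without single libraries (camera adjusted p = 0.198 without 0 h replicate 3, also over 0.05 without 0 h replicate 1 and 4 h replicate 3, range over alternatives 0.00176 to 0.25). Among replication-dependent histones, whose near-identical copies leave read assignment uncertain, 2 of 10 members fell (2 adjusted over the list alone; camera adjusted p = 0.00236, adjusted p = 0.0549 with an estimated correlation), and HIST1H2BK fell (-0.85 ± 0.16). With GC and length offsets, added after seeing the data, the list was not called (camera adjusted p = 0.111 with GC and length offsets, range over alternatives 0.000678 to 0.111) and neither was HIST1H2BK (-0.40, adjusted p = 0.298, range over alternatives 3.89e-05 to 0.298 by edgeR). For ribosomal proteins the median was -0.15 (camera adjusted p = 0.0178, adjusted p = 0.726 with an estimated correlation), and 0 of 60 members passed edgeR's test (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). That shift ended without single libraries and with GC and length offsets (camera adjusted p = 0.556 without 0 h replicate 1, also over 0.05 without 4 h replicates 1 and 2, range over alternatives 6.29e-06 to 0.726).

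Lists of S phase, G2/M and nuclear envelope genes had medians of 0.19, 0.23 and 0.28 at 4 h, shifts that camera called and that were lost without 0 h replicate 2. For S phase genes, 0 of 44 members passed edgeR's test (0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom), with camera adjusted p = 0.0378, adjusted p = 0.53 with an estimated correlation. Without that library the list had a median of 0.066 (camera adjusted p = 0.313 without 0 h replicate 2, also over 0.05 without 4 h replicate 3, range over alternatives 0.00968 to 0.53). For G2/M genes, 1 of 45 members rose (0 adjusted over the list alone), with camera adjusted p = 0.0171, adjusted p = 0.426 with an estimated correlation. Without the same library their median was 0.113 (camera adjusted p = 0.196 without 0 h replicate 2, range over alternatives 0.00422 to 0.426). For nuclear envelope and chromatin architecture, 1 of 48 members rose and 2 fell (1 and 2 adjusted over the list alone), with camera adjusted p = 0.0237, adjusted p = 0.53 with an estimated correlation (left-out values: camera adjusted p = 0.213 without 0 h replicate 2, also over 0.05 without 4 h replicate 1, range over alternatives 0.00732 to 0.53). Camera with GC and length offsets called neither G2/M genes (median 0.083, adjusted p = 0.146, range over alternatives 0.00422 to 0.426) nor the nuclear envelope list (median 0.143, adjusted p = 0.062, range over alternatives 0.00732 to 0.53). H1F0, a linker histone, fell (-1.84 ± 0.20) and LBR, the lamin B receptor, rose by 1.21 ± 0.22.

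At 4 h the largest declines were ranked among called genes at 10 CPM or more without overlap of the libraries. They also included OLIG1, a basic helix-loop-helix factor (-2.68 ± 0.36), HSPA7 (-3.10 ± 0.59), ATHL1 (-3.00 ± 0.59) and SPON2 (-2.48 ± 0.56). HSPA7 is a pseudogene close to HSPA6, so reads can be shared, and its edgeR call ended without 4 h replicate 2 (adjusted p = 0.0505 without 4 h replicate 2, range over alternatives 5.09e-18 to 0.0529). The edgeR calls of ATHL1 (adjusted p = 0.0587 without 4 h replicate 1, also over 0.05 without 4 h replicate 2, range over alternatives 3.76e-23 to 0.0587) and SPON2 (adjusted p = 0.106 without 4 h replicate 2, also over 0.05 without 0 h replicate 2 and 4 h replicate 1, range over alternatives 2.53e-23 to 0.106) also ended without single libraries. Genes fixed for every time had these edgeR values at 4 h: MPO, myeloperoxidase, 0.49 ± 0.21 (adjusted p = 0.174), ELANE, neutrophil elastase, -0.07 ± 0.30 (adjusted p = 0.902), and CYBB, the catalytic subunit of the phagocyte oxidase, 0.67 ± 0.19 (adjusted p = 0.0613). CEBPE, a factor of granulocyte maturation, stood at 0.08 ± 0.24 (adjusted p = 0.843) and MYC at 0.12 ± 0.20 (adjusted p = 0.733), also by edgeR. With GC and length offsets edgeR called ELANE (0.60, adjusted p = 0.00574, range over alternatives 0.00574 to 0.97), CEBPE (0.51, adjusted p = 0.0253, range over alternatives 0.0253 to 0.993) and CYBB (0.45, adjusted p = 0.0184, range over alternatives 0.00387 to 0.208), the last also called by DESeq2, without a filter on low counts and in both fits without 4 h replicate 3. ITGAM, the CD11b integrin, fell from 53.8 ± 5.77 to 37.2 ± 3.27 CPM (-0.53 ± 0.14, adjusted p = 0.0419 by edgeR), a call that ended without each of 4 libraries (adjusted p = 0.197 without 4 h replicate 2, also over 0.05 without 0 h replicates 2 and 3 and 4 h replicate 1, range over alternatives 0.000809 to 0.197).

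By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 790 of 12671 genes changed at 4 h, 254 higher and 536 lower, and 495 of them by at least 2-fold (130 higher and 365 lower). The libraries of both groups did not overlap in 25.5% of genes, where chance gives 10% on average over splits. A single split can lie far above that where many genes shift together. At an unadjusted p under 0.05 by edgeR, another split of these libraries gave up to 2224 genes, against 2389 for the real one. Of the 32 lists tested, 12 shifted at 4 h, 4 higher and 8 lower, and the estimated correlation kept 4 of them: retinoic acid response, Fc receptors, cholesterol and eosinophil markers. The lists of the primary granule, NADPH oxidase, interferon-stimulated genes, antigen presentation, integrated stress response, ribosome biogenesis and lysosome had medians of -0.18, -0.09, -0.16, -0.19, 0.10, 0.11 and 0.03, and camera called none of them (adjusted p from 0.0906 for ribosome biogenesis to 0.945 for lysosome). The lysosome mean was -0.03. Without 4 h replicate 1 camera called ribosome biogenesis (adjusted p = 0.0109, range over alternatives 0.00475 to 0.499) and the integrated stress response (adjusted p = 0.0379, range over alternatives 0.025 to 0.649), and without 0 h replicate 2 antigen presentation (adjusted p = 0.0477, range over alternatives 0.0151 to 0.512). With GC and length offsets it also called ribosome biogenesis and the integrated stress response, and without 0 h replicate 2, 4 h replicate 3 and 4 d replicate 1 it called lysosome genes lower (camera adjusted p = 0.0453, range over alternatives 0.0453 to 0.996). The count of changed genes was 476 without 0 h replicate 2, 340 without 4 h replicate 1, 254 without 4 h replicate 2 and 1519 without 4 h replicate 3, and 30 of 77 named calls ended without some library. It was 1350 with GC and length offsets (570 higher and 780 lower), 677 without 0 h replicate 2, 4 h replicate 1 (the library with reads in the most genes) and 4 d replicate 1, and 3192 with 4 h replicate 3 left out in place of 4 h replicate 1, all chosen after seeing the data. The last of these fits leaves out the library farthest from its group mates at each of 3 times, which lowers the spread within groups.

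**Figure D2:**
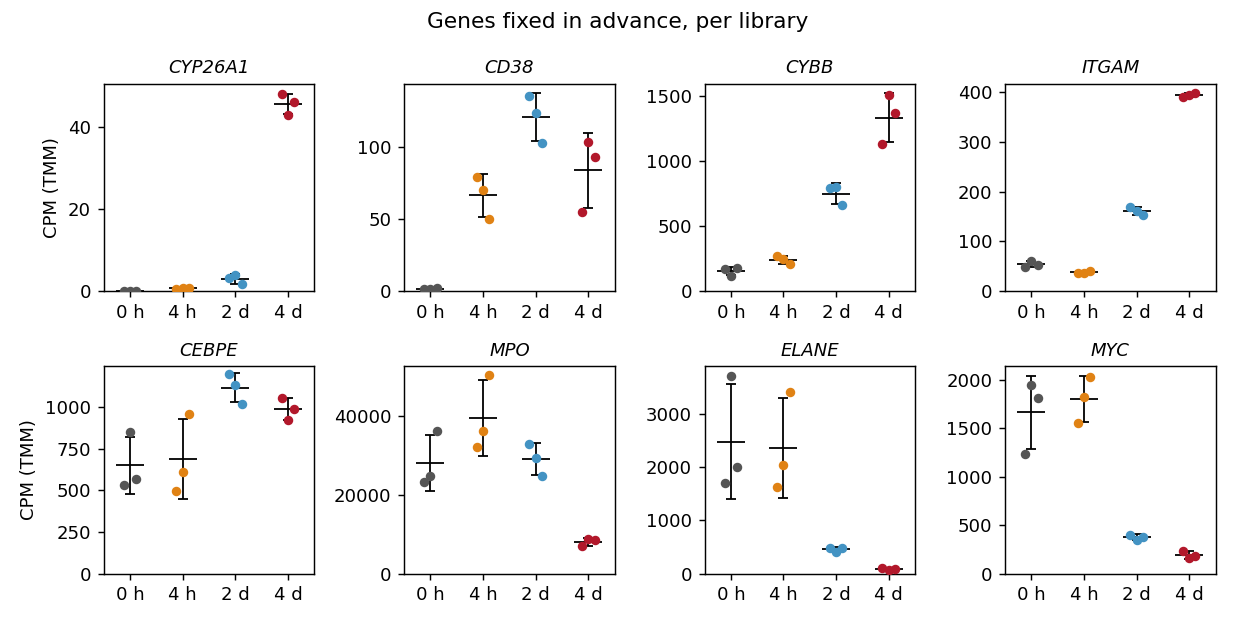
CPM of 8 genes fixed in advance in each library (points) at 0 h, 4 h, 2 d and 4 d of ATRA, with bars for mean ± SD (n = 3). CD38 stands at 1.48 CPM at 0 h and 66.3 at 4 h, while ELANE goes from 2475 at 0 h to 90.8 at 4 d.

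The comparison of 2 d with 0 h asked how far maturation had gone after 2 days. The lists of the retinoic acid response and of interferon-stimulated genes shifted higher and that of ribosome biogenesis lower, and other shifts at 2 d were lost with an estimated correlation. CYBB rose from 151 ± 32.0 CPM at 0 h to 750.2 ± 77.1 at 2 d (2.31 ± 0.20), ITGAM from 53.8 ± 5.77 to 161 ± 7.96 (1.58 ± 0.14) and CD38 to 121 ± 16.4 (6.35 ± 0.34), each with every 2 d library above every 0 h library. MYC fell from 1666 ± 378 to 378 ± 26.7 CPM (-2.14 ± 0.21) and ELANE from 2475 ± 1080 to 461 ± 44.0 (-2.42 ± 0.32), while MPO stood at 28000 ± 7009 and 28980 ± 4065 CPM (0.05 ± 0.21, adjusted p = 0.877 by edgeR). CEBPE rose by 0.78 ± 0.24 (adjusted p = 0.0215 by edgeR), a call that ended without each of 4 libraries (adjusted p = 0.0789 without 0 h replicate 1, also over 0.05 without 0 h replicate 3 and 2 d replicates 1 and 2, range over alternatives 3.64e-06 to 0.0789).

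In the retinoic acid response list 15 of 21 members rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 1.93 and camera adjusted p = 1.56e-08. At 2 d TGM2 had risen to 916 ± 205 CPM (11.47 ± 0.46) and HIC1 to 603 ± 126 (8.59 ± 0.35). DHRS3 was at least 816-fold higher than at 0 h, PTGES at least 599-fold higher, BATF2 at least 340-fold higher and CYP26A1 at least 33.1-fold higher; MLXIPL was 849-fold higher (95% counting interval 152 to 33600). Declines at 2 d were ranked among called genes at 10 CPM or more without overlap of the libraries. The largest were in IGLL1, a surrogate light chain of early B cells (-6.04 ± 0.43), and TERT, the catalytic subunit of telomerase (-5.93 ± 0.48). Next came MZB1, an endoplasmic reticulum protein of plasma cells (-4.76 ± 0.34), SPNS3 (-4.34 ± 0.32) and ASS1, which makes argininosuccinate (-3.98 ± 0.20).

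For NADPH oxidase genes, 4 of 9 members rose (4 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.00997, adjusted p = 0.133 with an estimated correlation). NCF1, with reads that pseudogenes can share, rose by 3.07 ± 0.32. Of the adhesion and chemotaxis receptors, 10 of 22 members rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.177 with an estimated correlation). ICAM1 rose by 4.28 ± 0.22 and the chemokine receptor CCR1 by 2.61 ± 0.20. Of the cytokine receptors, 15 of 27 members rose and 4 fell (16 and 5 adjusted over the list alone; camera adjusted p = 0.00217, adjusted p = 0.111 with an estimated correlation), among them CSF1R, the receptor of macrophage colony-stimulating factor, at 3.10 ± 0.19, and IL1RAP at 1.75 ± 0.33. Among lysosome genes, 23 of 36 members rose and 3 fell (23 and 3 adjusted over the list alone; camera adjusted p = 4.29e-06, adjusted p = 0.211 with an estimated correlation). CTSD, cathepsin D, rose by 3.35 ± 0.28 and TFEB, a regulator of lysosomal genes, by 2.57 ± 0.25. Of the interferon-stimulated genes, 26 of 41 members rose and 3 fell (26 and 3 adjusted over the list alone), with a median of 0.86 and camera adjusted p = 6.00e-07. IFIT1, IFI44L and OAS2, also in the list, had too few reads to be tested. OAS3, which senses double-stranded RNA, rose by 2.81 ± 0.32 and MX2, an antiviral GTPase, by 2.42 ± 0.19. In antigen presentation, 5 of 16 members rose (5 adjusted over the list alone; camera adjusted p = 0.0131, adjusted p = 0.169 with an estimated correlation). CTSS, cathepsin S, stood at 0.94 ± 0.20 and HLA-B at 0.83 ± 0.22, the latter uncertain because HLA genes share reads. For CDK inhibitors and growth arrest, 8 of 19 members rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0441, adjusted p = 0.135 with an estimated correlation), and BTG1 and BTG2, antiproliferative factors, rose, BTG1 from 95.5 ± 8.51 to 269 ± 18.6 CPM and BTG2 by 1.33 ± 0.18. This list's call ended without single libraries (camera adjusted p = 0.123 without 0 h replicate 2, also over 0.05 without 0 h replicate 1 and 2 d replicates 1, 2 and 3, range over alternatives 0.00938 to 0.135). Among Fc, complement and pattern receptors, 9 of 27 members rose and 4 fell (9 and 4 adjusted over the list alone), without a shift of the list (camera adjusted p = 0.148). The inhibitory receptor LILRB2 rose by 3.26 ± 0.24 and CD14 was lower than at 0 h (-2.45 ± 0.20).

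For ribosome biogenesis and MYC targets, 43 of 48 members fell (44 adjusted over the list alone), with a median of -1.15 and camera adjusted p = 2.83e-19. NME1, a nucleoside diphosphate kinase, fell (-2.15 ± 0.26), as did SRM, spermidine synthase (-1.99 ± 0.25). Of nuclear-encoded oxidative phosphorylation genes, 19 of 38 members fell (25 adjusted over the list alone; camera adjusted p = 9.48e-06, adjusted p = 0.345 with an estimated correlation). NDUFAB1 stood at -1.27 ± 0.17 and COX7B at -1.08 ± 0.23. Of the integrated stress response genes, 4 of 25 members rose and 16 fell (4 and 17 adjusted over the list alone; camera adjusted p = 9.30e-05, adjusted p = 0.156 with an estimated correlation). ASNS, asparagine synthetase, fell (-2.46 ± 0.25), as did PHGDH, which opens serine synthesis (-2.19 ± 0.20). In the cholesterol list 12 of 25 members fell (13 adjusted over the list alone; camera adjusted p = 0.000425, adjusted p = 0.109 with an estimated correlation). LSS, lanosterol synthase, stood at -1.45 ± 0.16 and CYP51A1 at -1.31 ± 0.19. Of heat shock and immediate early genes, 2 of 25 members rose and 10 fell (2 and 10 adjusted over the list alone; camera adjusted p = 0.0187, adjusted p = 0.136 with an estimated correlation). The chaperonin HSPE1 stood at -1.92 ± 0.27 and JUN at -1.72 ± 0.18. Among progenitor markers, 3 of 14 members rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.0352, adjusted p = 0.219 with an estimated correlation). GATA2 stood at -3.07 ± 0.24 and WT1 at -3.02 ± 0.23. The call of the progenitor list ended without single libraries (camera adjusted p = 0.0601 without 0 h replicate 3, also over 0.05 without 2 d replicates 2 and 3, range over alternatives 0.00679 to 0.219). Its median there was -0.667, -0.736 and -0.82, against -0.788 with all libraries. For eosinophil and basophil or mast markers, 1 of 9 members rose and 7 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.00201, adjusted p = 0.0574 with an estimated correlation). CCR3 rose by 6.53 ± 0.29 and PRG2, eosinophil major basic protein, fell (-3.75 ± 0.25). In the primary granule list 3 of 14 members rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.106). PRSS57, a serine protease, fell (-2.62 ± 0.30) and DEFA4, a defensin, rose by 2.17 ± 0.20.

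S phase and G2/M lists were not called by camera at 2 d. For S phase genes, 2 of 44 members rose and 8 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.148). For G2/M genes, 7 of 45 members rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.141). With GC and length offsets camera called G2/M genes higher, with a median of 0.245 (adjusted p = 0.0312, range over alternatives 0.0312 to 0.617). CCNE1, cyclin E, fell from 37.4 ± 2.85 to 18.7 ± 3.56 CPM and E2F8 rose by 0.83 ± 0.16. ASPM, a spindle pole protein, rose by 1.17 ± 0.21 and CDC25A, a phosphatase that activates CDKs, fell (-0.94 ± 0.15). The S phase list's median went from -0.18 to -0.352 without 0 h replicate 2, with a camera adjusted p of 0.012 (range over alternatives 0.00613 to 0.649). For nuclear envelope genes, 10 of 48 members rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0343, adjusted p = 0.559 with an estimated correlation). LBR stood at 1.82 ± 0.22 and PADI2, which converts arginine to citrulline, at 1.18 ± 0.17. The call of the nuclear envelope list ended without single libraries (camera adjusted p = 0.235 without 0 h replicate 2, also over 0.05 without 2 d replicates 1 and 2, range over alternatives 0.0112 to 0.559). Of the ribosomal proteins, 10 of 60 members fell (0 adjusted over the list alone; camera adjusted p = 0.000259, adjusted p = 0.596 with an estimated correlation), and this list's call ended with GC and length offsets (camera adjusted p = 0.138 with GC and length offsets, range over alternatives 2.00e-05 to 0.596). RPL38 and RPL12 fell by edgeR's test (-0.89 ± 0.23 and -0.76 ± 0.21). Both calls ended without 2 d replicate 1, with changes of -0.731 and -0.655. The edgeR value of RPL38 was adjusted p = 0.0535 without 2 d replicate 1, range over alternatives 0.000535 to 0.0535, and that of RPL12 adjusted p = 0.0723 without 2 d replicate 1, range over alternatives 0.000688 to 0.0723.

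By edgeR's test, 4512 genes changed at 2 d against 0 h, 2142 higher and 2370 lower, and 2122 of them by at least 2-fold (1042 higher and 1080 lower). The libraries of both groups did not overlap in 51% of genes, against 10% by chance. Camera called 17 of 32 lists, 9 higher and 8 lower, and the estimated correlation kept 3: retinoic acid response, ribosome biogenesis and interferon-stimulated genes. The glycolysis list's median was -0.14, its mean 0.12 and its direction in camera lower, with adjusted p = 0.8. Of the 122 named calls, 113 held without each library in turn.

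The comparison of 4 d with 0 h gave the changes at the end of the course. The lists of the retinoic acid response, Fc, complement and pattern receptors and interferon-stimulated genes shifted higher and that of ribosome biogenesis lower, and other shifts at 4 d were lost with an estimated correlation. ITGAM rose from 53.8 ± 5.77 CPM at 0 h to 395 ± 4.56 at 4 d (2.88 ± 0.15) and CYBB from 151 ± 32.0 to 1335 ± 190.5 (3.14 ± 0.21). ELANE fell from 2475 ± 1080 to 90.8 ± 18 CPM (-4.77 ± 0.36), MPO from 28000 ± 7009 to 8126 ± 1026 (-1.78 ± 0.22) and MYC from 1666 ± 378 to 193 ± 41.0 (-3.11 ± 0.22), with every 4 d library below every 0 h library. CD38 stood at 83.6 ± 25.7 CPM (5.82 ± 0.34), and CEBPE rose by 0.60 ± 0.24 (adjusted p = 0.0432 by edgeR), a call that ended without each of 5 libraries (adjusted p = 0.151 without 0 h replicate 1, also over 0.05 without 0 h replicate 3 and 4 d replicates 1, 2 and 3, range over alternatives 3.82e-05 to 0.151).

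In the retinoic acid response list 17 of 21 members rose and 3 fell (17 and 3 adjusted over the list alone), with a median of 2.91 and camera adjusted p = 2.97e-06. TGM2 reached 1080 ± 245 CPM (11.71 ± 0.46) and HIC1 793 ± 150 (8.98 ± 0.35). PTGES was at least 2390-fold higher than at 0 h, DHRS3 at least 1520-fold higher, BATF2 at least 953-fold higher, CYP26A1 at least 488-fold higher and DAAM2, a formin-related factor, at least 429-fold higher. TERT was 2200-fold lower (95% counting interval 395 to 87100), with 1 read left at 4 d. MZB1 fell (-7.50 ± 0.44), as did IGLL1 (-7.26 ± 0.48), SPNS3 (-6.24 ± 0.36) and ASS1 (-6.01 ± 0.23).

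Among Fc, complement and pattern receptors, 21 of 27 members rose and 3 fell (21 and 3 adjusted over the list alone), with a median of 1.53 and camera adjusted p = 1.77e-05. LILRB2 rose by 5.27 ± 0.26, CR1 by 4.12 ± 0.24, LILRB3 by 3.58 ± 0.30 and CLEC7A by 3.22 ± 0.21, with the LILRB genes uncertain because their family shares sequence. Of the adhesion and chemotaxis receptors, 14 of 22 members rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 7.45e-05, adjusted p = 0.117 with an estimated correlation). ICAM1 stood at 5.14 ± 0.22 and CCR1 at 3.28 ± 0.20. For NADPH oxidase genes, 5 of 9 members rose (5 adjusted over the list alone; camera adjusted p = 0.00495, adjusted p = 0.109 with an estimated correlation). NCF1 rose by 3.83 ± 0.33. Of the cytokine receptors, 20 of 27 members rose and 3 fell (21 and 3 adjusted over the list alone; camera adjusted p = 7.96e-05, adjusted p = 0.06 with an estimated correlation). CSF3R, the receptor of granulocyte colony-stimulating factor, rose by 2.55 ± 0.32. Among cytokines and chemokines, 14 of 25 members rose and 4 fell (14 and 4 adjusted over the list alone; camera adjusted p = 0.0268, adjusted p = 0.107 with an estimated correlation). CCL24, an eotaxin, rose by 6.70 ± 0.41 and CCL2 by 3.25 ± 0.19. This list was not called without 0 h replicate 2, 4 h replicate 3 and 4 d replicate 1 (camera adjusted p = 0.0596, range over alternatives 0.00777 to 0.107). Of the interferon-stimulated genes, 32 of 41 members rose and 3 fell (33 and 3 adjusted over the list alone), with a median of 1.69 and camera adjusted p = 1.56e-08. The list held 51 symbols, and the others had too few reads to be tested. Among them, reads in 4 d replicates 1, 2 and 3 were 5, 3 and 0 for IFIT1 and 0, 0 and 1 for IFI44L. They were 1, 0 and 1 for OAS2 and 7, 15 and 9 for RSAD2. MX2 rose by 3.90 ± 0.19 and OAS3 by 2.85 ± 0.32. In antigen presentation, 9 of 16 members rose (9 adjusted over the list alone; camera adjusted p = 0.00512, adjusted p = 0.133 with an estimated correlation). CD74, the invariant chain of class II molecules, stood at 1.88 ± 0.23 and CTSS at 1.78 ± 0.21. Genes of class II molecules themselves had too few reads to be tested, among them HLA-DRA, with 3 reads in each 4 d library. HLA-DRB1 and HLA-DPA1 had 0 reads there. Among lysosome genes, 25 of 36 members rose and 3 fell (25 and 4 adjusted over the list alone; camera adjusted p = 1.58e-05, adjusted p = 0.228 with an estimated correlation). CTSD rose by 4.32 ± 0.29 and TFEB by 3.68 ± 0.26. In the NF-kB list 17 of 28 members rose and 4 fell (17 and 4 adjusted over the list alone; camera adjusted p = 0.00333, adjusted p = 0.199 with an estimated correlation), among them ICAM1 and TNFAIP2 (2.91 ± 0.25).

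For monocyte and macrophage markers, 10 of 17 members rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0178, adjusted p = 0.238 with an estimated correlation). The scavenger receptor CD36 rose by 8.38 ± 0.43, CSF1R rose by 5.04 ± 0.19 and FCN1, ficolin, fell (-4.13 ± 0.29). CD163, MRC1, VCAN, MSR1 and C1QA, also in this list, had too few reads to be tested, with 0 in every 4 d library. For eosinophil and basophil or mast markers, 2 of 9 members rose and 6 fell (2 and 6 adjusted over the list alone), without a shift (camera adjusted p = 0.0814). CCR3 rose by 8.59 ± 0.30 and PRG2 fell (-4.67 ± 0.26). In the megakaryocyte list 5 of 8 members rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.176). THBS1, thrombospondin, stood at 9.07 ± 0.32 and ITGA2B at -1.87 ± 0.25. Of 5 measured erythroid markers, 2 fell, 2 adjusted over the list alone (camera adjusted p = 0.14), among them GYPC (-1.12 ± 0.18). Lymphoid markers had 4 measured members, too few for camera; 1 rose, 1 adjusted over the list alone, and 1 fell, 1 adjusted over the list alone, the latter CD79A (-1.01 ± 0.25). In the primary granule list 2 of 14 members rose and 9 fell (2 and 9 adjusted over the list alone), with a median of -2.05 and camera adjusted p = 0.00209, adjusted p = 0.217 with an estimated correlation. PRSS57 fell (-4.96 ± 0.34), as did CTSG, cathepsin G (-4.70 ± 0.22). In the secondary and tertiary granule list 9 of 18 members rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.148). CEACAM1 rose by 4.95 ± 0.19, with reads that paralogs can share, and ORM1, an acute phase protein, by 3.37 ± 0.30.

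For S phase genes, 42 of 44 members fell (42 adjusted over the list alone), with a median of -1.51 and camera adjusted p = 1.98e-13, adjusted p = 0.0769 with an estimated correlation. GINS2, part of the replicative helicase, fell (-2.43 ± 0.22), as did CCNE1 (-2.20 ± 0.23). For G2/M genes, 1 of 45 members rose and 28 fell (1 and 29 adjusted over the list alone; camera adjusted p = 7.45e-05, adjusted p = 0.211 with an estimated correlation). CDC25A stood at -2.32 ± 0.15 and the checkpoint protein MAD2L1 at -1.66 ± 0.18. Among CDK inhibitors, 6 of 19 members rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.426). BTG2 rose by 2.69 ± 0.19 and BTG1 by 2.06 ± 0.14. For ribosome biogenesis and MYC targets, 48 of 48 members fell (48 adjusted over the list alone), with a median of -1.93 and camera adjusted p = 4.65e-18. NME1 fell (-3.13 ± 0.27) and ODC1, which opens polyamine synthesis, stood at -2.95 ± 0.21. Of the ribosomal proteins, 53 of 60 members fell (53 adjusted over the list alone; camera adjusted p = 4.34e-09, adjusted p = 0.409 with an estimated correlation). RPS18, whose copies can share reads, stood at -1.73 ± 0.28 and RPS29 at -1.35 ± 0.36. Of nuclear-encoded oxidative phosphorylation genes, 32 of 38 members fell (35 adjusted over the list alone; camera adjusted p = 6.92e-07, adjusted p = 0.278 with an estimated correlation). ATP5J stood at -1.64 ± 0.21 and NDUFAB1 at -1.54 ± 0.17. In the cholesterol list 15 of 25 members fell (15 adjusted over the list alone; camera adjusted p = 0.0034, adjusted p = 0.158 with an estimated correlation). CYP51A1 stood at -1.48 ± 0.20. Of the integrated stress response genes, 5 of 25 members rose and 16 fell (5 and 16 adjusted over the list alone; camera adjusted p = 0.00139, adjusted p = 0.219 with an estimated correlation). PHGDH fell (-3.82 ± 0.22), as did PSAT1, the next enzyme of serine synthesis (-3.40 ± 0.24). Among progenitor markers, 2 of 14 members rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.0358, adjusted p = 0.219 with an estimated correlation). WT1 stood at -4.86 ± 0.27 and GATA2 at -4.07 ± 0.26. The progenitor list's call ended without 4 d replicate 1 (camera adjusted p = 0.0714 without 4 d replicate 1, range over alternatives 0.0128 to 0.219). Of replication-dependent histones, 7 of 10 members rose (7 adjusted over the list alone; camera adjusted p = 0.00896, adjusted p = 0.0822 with an estimated correlation). HIST1H2BK stood at 1.58 ± 0.15.

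By edgeR's test, 7330 genes changed at 4 d against 0 h, 3563 higher and 3767 lower, and 4460 of them by at least 2-fold (2230 higher and 2230 lower). The libraries of both groups did not overlap in 59% of genes, against 10% by chance. Camera called 21 of 32 lists, 12 higher and 9 lower, and the estimated correlation kept 4: retinoic acid response, Fc receptors, ribosome biogenesis and interferon-stimulated genes. Myeloid transcription factors went both ways, as 20 of 43 members rose and 14 fell (20 and 15 adjusted over the list alone; camera adjusted p = 0.396). GATA2 fell (-4.07 ± 0.26), as did MYC (-3.11 ± 0.22). For apoptosis regulators, 14 of 31 members rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.0814). PMAIP1, a BH3-only protein, rose by 3.18 ± 0.26 and BCL2A1 by 2.61 ± 0.18. Camera called the list of apoptosis regulators higher with GC and length offsets (adjusted p = 0.0379, range over alternatives 0.0379 to 0.211). Among chromatin modifiers, 17 of 47 members rose and 15 fell (17 and 17 adjusted over the list alone; camera adjusted p = 0.878; median -0.06, mean 0.02). The DNA methyltransferase DNMT3A rose by 2.31 ± 0.17 and the arginine methyltransferase PRMT1 fell from 408 ± 38.5 to 102 ± 10.8 CPM. For the nuclear envelope list, 12 of 48 members rose and 17 fell (12 and 20 adjusted over the list alone; camera adjusted p = 0.541). PADI2 stood at 2.37 ± 0.18 and LBR at 1.92 ± 0.22. For glycolysis, 9 of 27 members rose and 15 fell (9 and 15 adjusted over the list alone; camera adjusted p = 0.515; median -0.76, mean 0.00). FBP1 stood at 3.17 ± 0.21 and SLC2A5 at 2.90 ± 0.24. For heat shock and immediate early genes, 6 of 25 members rose and 11 fell (6 and 11 adjusted over the list alone; camera adjusted p = 0.35). FOS stood at 2.43 ± 0.18 and HSPE1 at -2.42 ± 0.28. Of the 127 named calls, 126 held without each library in turn.

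**Figure D3:**
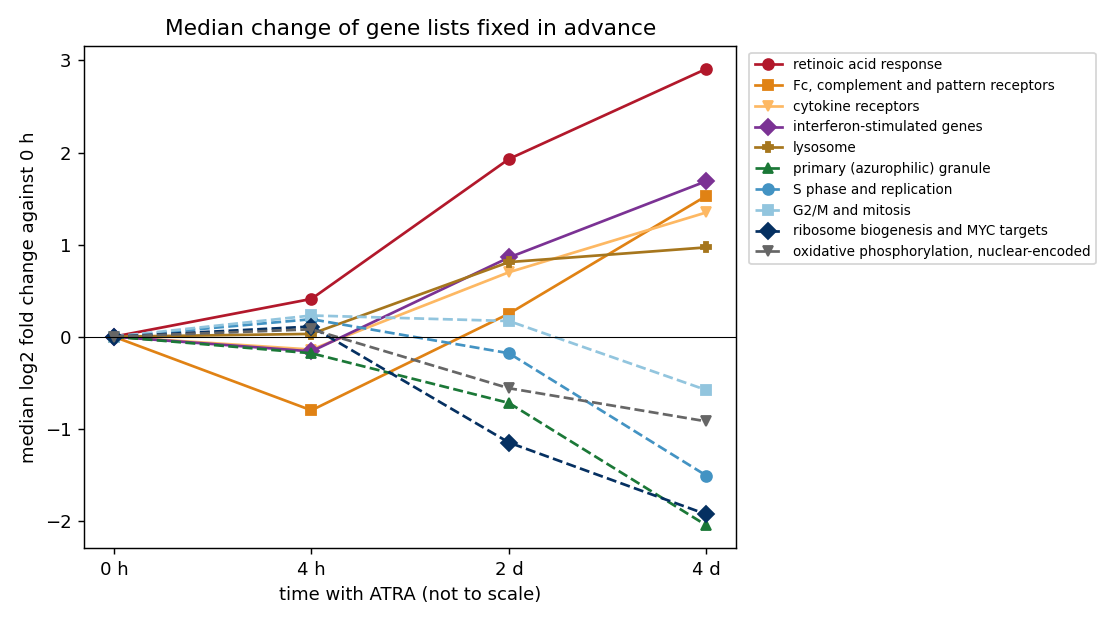
Median log2 fold change against 0 h of 10 gene lists at 4 h, 2 d and 4 d, 1 line per list. Fc, complement and pattern receptors go from -0.80 at 4 h to 1.53 at 4 d, and ribosome biogenesis and MYC targets from 0.11 to -1.93.

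The step from 4 h to 2 d separated the immediate from the later response. CCL24 rose by 8.13 ± 0.47, ALS2CL by 6.07 ± 0.36 and IHH, a hedgehog ligand, by 5.29 ± 0.29, while OSM, which had risen by 4 h, fell (-7.69 ± 0.43), as did IGLL1 (-5.25 ± 0.42) and TERT (-5.13 ± 0.48). Fc, complement and pattern receptors were higher than at 4 h: 18 of 27 members rose (18 adjusted over the list alone), with a median of 1.09 and camera adjusted p = 4.47e-08. For ribosome biogenesis and MYC targets, 47 of 48 members fell (47 adjusted over the list alone; camera adjusted p = 1.20e-22). Of the interferon-stimulated genes, 25 of 41 members rose and 1 fell (26 and 2 adjusted over the list alone; camera adjusted p = 9.37e-09). Among monocyte and macrophage markers, 11 of 17 members rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 7.43e-05, adjusted p = 0.0857 with an estimated correlation). Among lysosome genes, 22 of 36 members rose and 1 fell (24 and 2 adjusted over the list alone; camera adjusted p = 2.70e-06, adjusted p = 0.211 with an estimated correlation). For S phase genes, 1 of 44 members rose and 13 fell (1 and 12 adjusted over the list alone; camera adjusted p = 0.00334, adjusted p = 0.409 with an estimated correlation). By edgeR's test 4377 genes changed, 2094 higher and 2283 lower, and 2140 of them by at least 2-fold (1203 higher and 937 lower). The libraries did not overlap in 53.1% of genes, against 10% by chance. Camera called 19 lists, 13 higher and 6 lower, of which 4 held with an estimated correlation: retinoic acid response, Fc receptors, ribosome biogenesis and interferon-stimulated genes. Median and mean differed in sign for glycolysis (-0.28 and 0.04), cholesterol (-0.16 and 0.01) and chromatin modifiers (0.03 and -0.01), none of them called by camera (adjusted p = 0.591, 0.733 and 0.859).

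Between 2 d and 4 d the replication and mitosis genes fell together. For S phase genes, 43 of 44 members fell (44 adjusted over the list alone), with a median of -1.29 and camera adjusted p = 2.28e-26. For G2/M genes, 41 of 45 members fell (45 adjusted over the list alone), with a median of -0.79 and camera adjusted p = 2.30e-15. DAAM2 rose by 3.97 ± 0.44, CYP26A1 from 2.90 ± 1.19 to 45.6 ± 2.51 CPM (3.93 ± 0.26) and SLC26A11, an anion transporter, by 3.79 ± 0.40. TERT was 34.9-fold lower (95% counting interval 5.90 to 1420) at 4 d than at 2 d, CES1, a carboxylesterase, fell (-2.98 ± 0.41), and RGCC, a cell cycle regulator, fell (-2.87 ± 0.30). In the primary granule list 11 of 14 members fell (11 adjusted over the list alone; camera adjusted p = 3.70e-07, adjusted p = 0.0769 with an estimated correlation). MPO and ELANE, added to this step after their values were seen, fell (-1.83 ± 0.22 and -2.35 ± 0.32). Among Fc, complement and pattern receptors, 20 of 27 members rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 7.94e-11). Of the interferon-stimulated genes, 18 of 41 members rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 1.77e-06). Of replication-dependent histones, 7 of 10 members rose (7 adjusted over the list alone; camera adjusted p = 0.000592). By edgeR's test 3374 genes changed, 1660 higher and 1714 lower, and 1470 of them by at least 2-fold (854 higher and 616 lower). The libraries did not overlap in 48% of genes, against 10% by chance. Camera called 21 lists, 13 higher and 8 lower, and the estimated correlation kept 8: Fc receptors, cytokine receptors, cytokines, S phase, G2/M, ribosome biogenesis, interferon-stimulated genes and histones. The count of changed genes was 2245 without 2 d replicate 1 and 2110 without 2 d replicate 2.

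**Figure D4:**
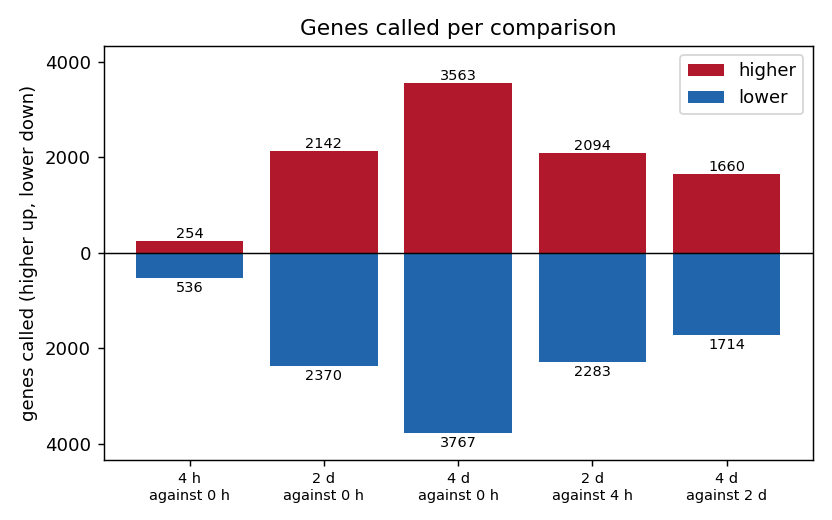
Number of genes called by edgeR's test in each of the 5 comparisons, with genes that were higher as bars above 0 and genes that were lower as bars below 0. The bars grow from 254 and 536 genes at 4 h to 3563 and 3767 at 4 d against 0 h.

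Over the whole course 8006 of 12671 genes changed at some time by edgeR's F-test. Of the 790 genes changed at 4 h, 343 had changed the same way at 4 d, 172 higher and 171 lower, and 243 the opposite way, 214 of them lower at 4 h and higher at 4 d (74 such genes without 4 h replicate 2 and 100 without 4 h replicate 1). CLEC7A, CR1 and ITGAX were among the 214, and ITGAX stood at -2.15 ± 0.35 at 4 h and 2.60 ± 0.35 at 4 d. Independent lists of these sizes would share 230.8 genes in the same direction, 71.4 both higher and 159.3 both lower. They would share 226.2 in opposite directions, 150.7 lower and then higher and 75.5 higher and then lower, where 29 were found. In 100 simulations of unchanged groups, all 12 libraries were drawn from the 0 h means, each gene on its own. There edgeR called 0.01 genes on average in the same direction and 0 in opposite directions. At an unadjusted p under 0.05 these simulations gave 128 and 0.84, and DESeq2 and limma-voom were not run on them. The low counts in opposite directions decide nothing, because chance values of the shared 0 h libraries move both comparisons the same way. The covariance of the fold changes across genes was 0.277, against a simulated 0.0447. Splitting the 0 h libraries would leave fewer than 2 in a part, so part of the shared calls can come from the shared 0 h libraries. At 2 d and 4 d, 4075 genes had changed the same way and 30 opposite ways. A further 3225 genes were called at 4 d and not at 2 d, 407 at 2 d and not at 4 d, and 129 at 4 h alone, differences that were not tested themselves. The overlap in the same direction was 209 without 0 h replicate 2, 129 without 4 h replicate 2, 701 without 4 h replicate 3, 522 with GC and length offsets and 1491 without 0 h replicate 2, 4 h replicate 3 and 4 d replicate 1.

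The first and the last step share no library. Across 12671 genes, the fold change from 0 h to 4 h and that from 2 d to 4 d had a Pearson r of -0.188 and a Spearman rho of -0.282. Genes are not independent replicates, so no p is given. Genes lower in the first step and higher in the last numbered 243, against 70.2 for independent lists, and genes higher in both 60, against 33.3. Genes lower in both numbered 34, against 72.5, and genes higher in the first and lower in the last 46, against 34.4. CD14 was lower in the first step (-2.84 ± 0.20) and higher in the last (1.86 ± 0.20), and FPR1 went from 10.4 ± 1.56 to 3.24 ± 0.422 CPM in the first and from 5.54 ± 0.602 to 23.9 ± 2.68 in the last. Both were named by the rule at 4 h and chosen for this comparison after their values were seen. The correlation was -0.062 without 0 h replicate 2, -0.061 without 4 d replicate 1 and -0.295 without 4 h replicate 1. It was 0.021 without 0 h replicate 2, 4 h replicate 3 and 4 d replicate 1, so its sign rested on which libraries were kept.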

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

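The tests on length, on the 10 genes with the most reads, on the other 4 h libraries, on GC content, on the libraries left out singly and in 2 sets of 3 and on genes 4-fold higher at 4 d were chosen after the results were seen, and those on the shared 0 h libraries before. The bounds for the 2 sets were changed after the values were seen: earlier bounds, on the median log2 change at 4 h and on the number of such genes, had been met against both sets, and were replaced by the share of the genes that kept both calls.

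Of the tested genes, 214 were lower at 4 h and higher at 4 d than at 0 h, among them CLEC7A (-2.45 ± 0.25 and 3.22 ± 0.21) and CR1 (-1.32 ± 0.23 and 4.12 ± 0.24), and 193 of them were called higher at 2 d than at 4 h. GC content and length trends between libraries, as far as the offsets fit them, are argued against as the whole cause. With offsets 183 of the 214 (85.5%) kept both calls. The offsets also added 149 other such genes, so they can make calls easier, and a part of the changes can still follow GC content. The median GC content of the 214 was 55.4%, against 48.7% over tested genes. Libraries left out together decide nothing: 147 of the 214 kept both calls without 0 h replicate 2, 4 h replicate 1 and 4 d replicate 1, with 211 such genes in all, and 202, with 593 in all, with 4 h replicate 3 left out in place of 4 h replicate 1, a choice of the library farthest from its mates in 3 groups that lowers the spread within groups. A single library cannot be told apart from an effect of ATRA: 100 such genes were called anew without 4 h replicate 1 and 74 without 4 h replicate 2, and a fit to fewer libraries can miss genes, while the 214, chosen with these libraries, had a median log2 change at 4 h of -1.11 and -1.13 there against -1.17. Simulations of unchanged groups on the shared 0 h libraries met a bound set before, with a mean of 0 such genes by edgeR (0.4 at an unadjusted p under 0.05, DESeq2 and limma-voom not run), but decide nothing, because chance values of those libraries move both comparisons the same way. Fewer spontaneously mature cells in the 4 h cultures cannot be told apart from an early effect of ATRA either, and time in culture and handling stay open without untreated libraries: the 871 genes at least 4-fold higher at 4 d had a median of 0.16 and quartiles of -0.48 and 0.93 at 4 h (62 called lower and 95 higher), and a first bound, a median of 0 or higher against this explanation, was met but was replaced after the value was seen by one on the lower quartile, because these genes go both ways.

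In 4 h replicate 1, 4260 genes had reads, 14083 in all, that had none in the other 11 libraries, and 28.15% of its reads lay outside genes, against at most 20.76% at 0 h. Genomic DNA in the library could give them and stays open: reads per kb of transcript were level over 5 length classes of 3607 genes longer than 1 kb (highest to lowest 1.16), with a Spearman rho of 0.624 between reads and length across genes. RNA of another cell type is argued against, since the 10 genes with the most reads held 1.85% of these reads and the most in 1 gene was 50. The other 4 h libraries held at most 27 such genes, which decides little, since a gene read in 2 libraries cannot count. Genes with at least 1 read, compared after the values were seen, numbered 15446 and 15245 in 4 h replicates 2 and 3, against 22265. These totals argue against an effect of ATRA for 4 h. At 0.939 reads per kb, such DNA could make up a median of 1.25% of a tested gene's reads in that library, and over 10% for 1952 of 11971 genes.

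The share of reads outside genes was above the highest at 0 h (20.76%) in 4 further libraries: 21.62% in 2 d replicate 3 and 21.22%, 23.25% and 22.14% in 4 d replicates 1, 2 and 3. In 4 d replicate 3, 52 genes had reads found in no other library, against at most 45 in a 0 h library. No explanation was tested for these values.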

How the results depend on the processing

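GC and length offsets, a fit without 0 h replicate 2, 4 h replicate 1 and 4 d replicate 1 (set 1) and a fit without 0 h replicate 2, 4 h replicate 3 and 4 d replicate 1 (set 2) were chosen after seeing the data. The cause of the changes below was not tested, except that a stricter threshold and a fold limit call fewer results by construction.

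Of the gene counts in the 5 comparisons, that at 4 h against 0 h, 790, depended most on the processing: 1960 without a filter on low counts, 381 with replicate number as a term, 261 with the 6 libraries alone, 1350 with GC and length offsets (570 higher and 780 lower), 241 at an adjusted p under 0.01 and 495 at 2-fold or more. Leaving out each library in turn gave 254 to 1519: 476 without 0 h replicate 2, 340 without 4 h replicate 1, 254 without 4 h replicate 2 and 1519 (796 higher and 723 lower) without 4 h replicate 3. The count was 677 without set 1 and 3192 (1573 higher and 1619 lower) without set 2. DESeq2 called 1180 genes, among them 765 of the 790; of those 790, GC and length offsets kept 701, the fits without set 1 and set 2 510 and 754, and the replicate term 380. The share of calls that were higher was 32.2%, 42.2% with GC and length offsets and 24% with library totals.

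For 2 d against 0 h the count was 2705 at an adjusted p under 0.01 and 2122 at 2-fold or more, and for 4 d against 0 h 4460 at 2-fold or more. For 2 d against 4 h it was 2711 and 2140, and for 4 d against 2 d 1745 and 1470. Without 2 d replicate 1 and 2 d replicate 2 the last count was 2245 and 2110, within a range of 2110 to 2798. Without set 2 the counts were 8719 for 4 d against 0 h, 6725 for 2 d against 4 h and 5549 for 4 d against 2 d. The other alternatives left the counts of these 4 comparisons within 1.5 times.

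Shifted lists numbered 12, 17, 21, 19 and 21 in the 5 comparisons with the preset correlation and 4, 3, 4, 4 and 8 with the estimated one. Genes changed the same way at 4 h and 4 d numbered 171 with the replicate term, 522 with GC and length offsets, 197 at 2-fold or more and 129 (without 4 h replicate 2) to 701 (without 4 h replicate 3) with a library of 0 h, 4 h or 4 d left out. Opposite changes numbered 121, 501 and 120 under the first 3 of these, and genes lower and then higher 110, 332 and 113. With a library left out these 2 ran from 80 to 378 and from 74 to 271, the 4 h and 4 d libraries being added after seeing the data. Without set 2 the 3 numbers were 1491, 907 and 593. The correlation of the first and last steps ran from -0.295 to -0.061 with libraries left out in turn, and changed sign without set 2, 0.021 against -0.188.

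ELANE at 4 h alone changed sign with a call: 0.598 with GC and length offsets (edgeR adjusted p = 0.00574, range over alternatives 0.00574 to 0.97), against -0.07. Of 354 results for named genes, direction and call were the same in 354 with RLE factors, 351 with library totals, 353 with DESeq2, 352 with limma-voom, 348 without a filter and 334 with the replicate term. With GC and length offsets 342 were the same, 6 lost and 5 gained the call, and 349 and 352 were the same without set 1 and set 2. Of 160 list results, 160 were the same with RLE factors, 156 with library totals, 159 with the replicate term and 148 with GC and length offsets (6 lost and 6 gained), with 146 and 144 without set 1 and set 2. The estimated correlation kept 93 and lost 67. Scaling moved the median log2 change over all genes to at most 0.067. No pairing by replicate number was seen: the 18 correlations of same-number deviations ran from -0.809 to 0.671 (mean -0.184, others 0.125). Of these, 6 were over 0.1, and 2 libraries were closest to one of their own number. The labels do not state a pairing, and trends shared by many genes, such as that on GC content, could mask one. Depth limited genes near the filter, and genes with 0 reads at 0 h have only bounds.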

Other observations

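Of the genes of amino acid metabolism, 6 were chosen after their values were seen and are not a tested list. ASS1 was the reason, being among the largest declines by the naming rule. At 2 d and 4 d against 0 h, log2 fold changes were -3.98 ± 0.20 and -6.01 ± 0.23 for ASS1 (arginine), -2.19 ± 0.20 and -3.82 ± 0.22 for PHGDH (serine) and -1.57 ± 0.22 and -3.40 ± 0.24 for PSAT1 (serine). They were -2.89 ± 0.27 and -4.01 ± 0.29 for PYCR1 (proline), -2.43 ± 0.17 and -4.03 ± 0.18 for GPT2 (alanine) and -1.67 ± 0.21 and -4.09 ± 0.25 for BCAT1 (branched-chain amino acids). At 4 h edgeR called none of them: ASS1 0.42 ± 0.17, PHGDH 0.10 ± 0.19, PSAT1 0.71 ± 0.21, PYCR1 -0.40 ± 0.24, GPT2 -0.03 ± 0.16 and BCAT1 0.68 ± 0.20, with adjusted p from 0.0648 (PSAT1) to 0.929 (GPT2).

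Of 22 symbols of interferon genes, 15 had reads in 4 h replicate 1, 32 reads in all, in a library that held 14083 reads in 4260 genes without a read elsewhere, and 1 read fell in 4 d replicate 1. The other 10 libraries had 0 reads in them.

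Within-group SD of log2 CPM had a median of 0.24 over genes at a mean of 10 CPM or more, and was 1.86 and 0.99 for VARS and BAG6 of the major histocompatibility complex. HLA-B and HLA-C, of the same region, had an SD of 0.27 and 0.22. DEFA1 and DEFA3, which are near-identical, had 0 reads in every library.

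Splits of the libraries into other groups were counted for each comparison, a test fixed before the data were examined. Of 100 splits of the 12 libraries into 4 groups of 3, 1 (the real one) gave as many genes changed at any time. It gave 8006, against at most 2936 in the others (8579 and 4917 at an unadjusted p under 0.05). These splits treat libraries as independent, which the labels neither state nor exclude, so chance differences between cultures are not excluded. For each pair of times, 6 libraries make 10 splits, too few for a share under 0.05, and 1 of the 10 gave as many genes, the real one. Real counts by edgeR were 261, 4324, 6341, 5160 and 4005 for 4 h, 2 d and 4 d against 0 h, 2 d against 4 h and 4 d against 2 d, and the highest other count was 0 in each. At an unadjusted p under 0.05 the real splits gave 2389, 5596, 7136, 6125 and 5319 and the highest others 2224, 472, 688, 359 and 647, and DESeq2 and limma-voom were not run on the splits.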
